A study of Homo sapiens with 6 samples.

How the data were processed

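RNA sequencing was done on 6 samples of HEK293A cells, 3 given the DMSO vehicle and 3 given 20 nM VT01454, each for 2 h. Total RNA was purified with an RNeasy Plus kit and libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols. The submitters' processing notes name HISAT2 2.2.1, HTSeq 0.9.1 and the genome build hg38. The annotation release, the strand setting, read trimming and the treatment of reads with several positions are not given in the sources used here. The deposited values are raw read counts per Ensembl gene, 1 table per sample, with no normalization; the tables held whole numbers for 60676 gene IDs and no lines for unassigned reads, so the share of unassigned reads is unknown. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

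Gene symbols were matched to 60357 of the 60676 IDs, and 58503 IDs were found in GENCODE release 29, which is on the same genome build and gave coordinates, gene types, exonic length and GC content. Coordinates are 1-based. Total counts ran from 19126039 to 28880374 per library, and 1 count was worth 0.0346 to 0.0523 CPM (counts scaled to a library total of 1e+06). A count of 0 allowed up to 3 counts, or 0.104 to 0.157 CPM, as counting error only. All 37 mitochondrially encoded genes in the tables were at 0 in every library. Counts of antisense and divergent transcripts, and of genes with near-identical copies such as those for ribosomal proteins, are uncertain because the counting settings are not given.

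The main comparison used edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, which held 99.9% of all counts in each library, TMM factors were computed, and the quasi-likelihood F-test with robust dispersion was run two-sided on compound against vehicle. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p below 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM values are counts divided by TMM-scaled library sizes, given as mean ± SD over 3 libraries. Exact two-sided permutation tests were used for library totals and composition; with 3 against 3 libraries these cannot give a p below 0.1.

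A total of 28 gene lists were fixed from memory before the data were examined, as were the tests, the first set of alternatives below and the rule for naming genes. The lists cover YAP/TAZ-TEAD targets, Hippo pathway components, PITP and phosphoinositide metabolism, SRF/MRTF and cytoskeletal genes, immediate early genes, ERK feedback genes, FOXO targets, cholesterol biosynthesis, fatty acid synthesis, the unfolded protein response, the integrated stress response, p53 targets, heat shock, hypoxia and glycolysis, NF-kB, TGF-beta and BMP, Wnt and Notch targets, lysosome and autophagy genes, G1/S and G2/M genes, interferon-stimulated genes, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, replication-dependent histones, and markers of leukocytes, of fibroblasts and endothelium, and of squamous and cervical epithelium. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with an inter-gene correlation of 0.01, adjusted over the 25 lists so tested; camera with an estimated correlation and fry were run beside it. Genes are named by 3 rules: the 12 largest rises and 12 largest falls among changed genes with a proper symbol, a mean of at least 1 CPM and groups that do not overlap; 11 genes of the Hippo and PITP question, whatever their result; and up to 4 members of each list by smallest p. Genes outside these rules are said to have been chosen after their values were seen.

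The pipeline was tested on simulated counts made from the real means and library sizes of compound against vehicle, over 15342 genes with 200 changed genes. It recovered 38% of genes seeded at 1.3-fold, 68% at 1.5-fold, 74% at 2-fold and 100% at 3-fold, with 5 false calls among 145. Each gene was drawn independently, so deviations shared by many genes of a library were not simulated. These shares may therefore not hold for the real libraries. The first set of alternatives was DESeq2 1.42.0, DESeq2 size factors, library size alone, no count filter, a filter at a mean of 1 CPM, the replicate number as a block, limma-voom, leaving out each library in turn, a fold threshold of 1.5 and a stricter adjusted p of 0.01. Added after the data were seen were thinning to the smallest library, offsets for GC content and gene length (available for 99.3% of tested genes), a covariate for genes counted in only 4 libraries, leaving out 2 compound libraries, and a term for 3 pairs of libraries defined from 17 genes near 0 in exactly 2 or 4 libraries.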

Results

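Transcript levels were measured by RNA sequencing in HEK293A cells, an adherent derivative of the human embryonic kidney line HEK293, after 2 h with vehicle (DMSO, n = 3 libraries) or with 20 nM VT01454 (n = 3 libraries), a compound known here by its code name. The vehicle libraries held 20962083, 19126039 and 26879796 counts and the compound libraries 28880374, 25066990 and 24646466. Group means of 22322639 and 26197943 did not differ beyond the spread between libraries (exact two-sided permutation p = 0.3, smallest possible 0.1). No pair of libraries agreed within sampling noise: chi-square per degree of freedom ran from 1.99 between compound libraries 2 and 3 to 17.9 between vehicle libraries 2 and 3. Pairs of vehicle libraries stood at 7.16 to 17.9, pairs of compound libraries at 1.99 to 2.66 and pairs across the groups at 6.91 to 16.3. The series title sets the compound in work on phosphatidylinositol transfer proteins (PITPs), phosphoinositides and the Hippo pathway, a kinase cascade that restrains the co-activators YAP and TAZ. The comparison of compound with vehicle therefore asks which transcripts, those of YAP/TAZ targets among them, differ after 2 h of treatment.

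After 2 h with the compound a small set of classical YAP/TAZ target transcripts was lower and many immediate early transcripts were higher than with vehicle. AMOTL2, which encodes an angiomotin family scaffold of the Hippo pathway, was 3.11-fold lower, and CCN2, which encodes the matricellular protein CTGF, was 2.199-fold lower. The zinc finger transcription factor genes EGR3 and EGR1 were 28.4-fold and 10.5-fold higher, and FOS, a subunit of AP-1, was 4.80-fold higher. In all, 294 of 15577 tested genes changed at an adjusted p below 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 198 higher and 96 lower. Of these, 60 were higher and 32 lower by at least 1.5-fold, and the median log2 fold change of all tested genes was −0.0073.

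**Figure D1:**
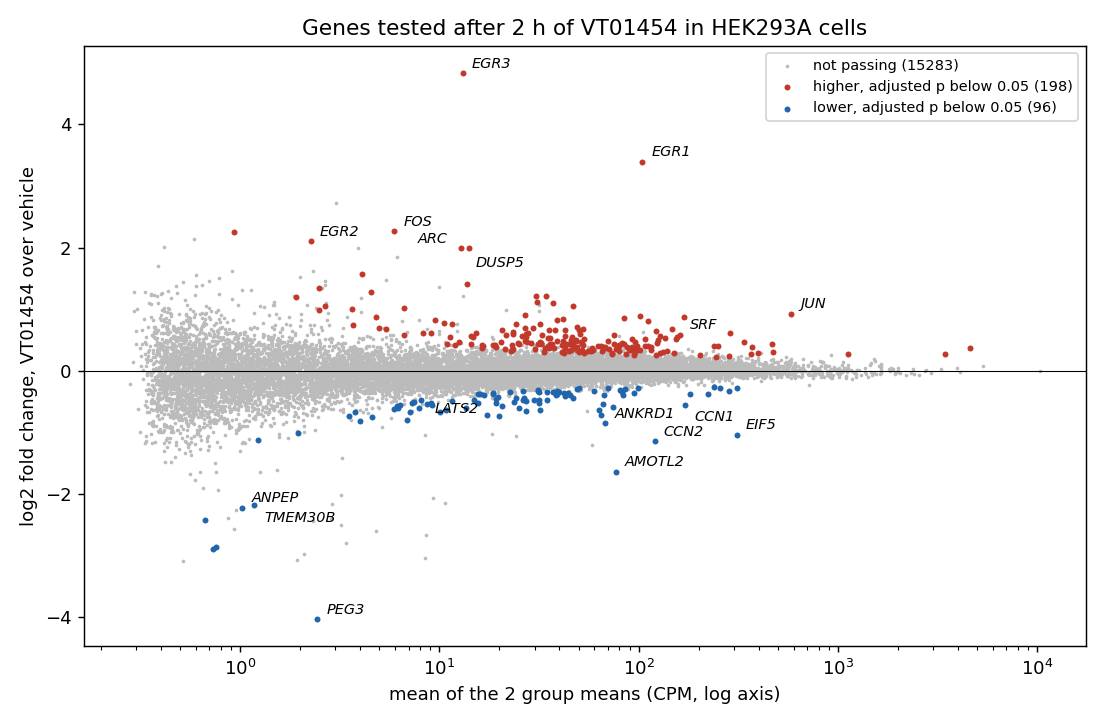
Log2 fold change of each tested gene (compound over vehicle) against the mean of the group means in CPM on a log axis, with 198 genes higher (red) and 96 lower (blue) at an adjusted p below 0.05. EGR3 and EGR1 stand at the top at 4.83 and 3.39, and AMOTL2 and CCN2 lie below the band of unchanged abundant genes at −1.64 and −1.14.

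Of the 22 YAP/TAZ-TEAD targets on the list, 5 fell, none rose and 17 did not pass. AMOTL2 (chromosome 3, 134355874 to 134375479) went from 116 ± 7.15 to 37.4 ± 0.860 CPM (SD, n = 3 each), a log2 fold change of −1.64 ± 0.07 (SE, adjusted p = 3.97e-08). CCN2 (chromosome 6, 131948176 to 131951373) went from 165 ± 7.15 to 75.1 ± 0.549 CPM (−1.14 ± 0.06, adjusted p = 4.47e-07). ANKRD1, which encodes a nuclear ankyrin repeat protein, fell 1.80-fold from 87.5 to 48.4 CPM, and CCN1, which encodes the CYR61 protein, fell 1.46-fold from 204 to 139 CPM. LATS2, the gene of a Hippo kinase that is itself a YAP target, fell 1.37-fold (−0.45 ± 0.09, adjusted p = 0.0255). Adjusted over the list alone, 5 members were lower and 1 higher. Members did not share a direction, with 10 of 22 above 0: the median log2 fold change was −0.071 and its mean −0.17, and AXL, a receptor tyrosine kinase gene, stood at 0.027 ± 0.16 (adjusted p = 0.954). Without vehicle library 3, 3 members were higher and 6 lower, and without vehicle library 2, 1 was higher and 5 lower. Against all other genes the list was shifted down by camera with the preset correlation (adjusted p = 0.00836), with adjusted p = 0.206 with an estimated correlation, and adjusted p = 0.116 without vehicle library 3. LATS2 did not pass when vehicle library 1 or any single compound library was left out (adjusted p up to 0.189), while AMOTL2, CCN2, ANKRD1 and CCN1 passed without any single library.

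Immediate early genes, which respond to growth factors or stress within an hour, showed the broadest rise: 23 of 30 tested members rose, 1 fell and 6 did not pass. Adjusted over the list alone, 24 were higher and 1 lower. EGR3 (chromosome 8, 22687659 to 22693302) went from 0.920 ± 0.373 to 25.2 ± 2.03 CPM, a log2 fold change of 4.83 ± 0.19 (adjusted p = 3.97e-08). EGR1 (chromosome 5, 138465490 to 138469315) went from 18.3 ± 5.48 to 189.8 ± 3.20 CPM (3.39 ± 0.18, adjusted p = 1.09e-04). EGR2 rose 4.31-fold, the synaptic and cytoskeletal gene ARC 3.98-fold, the AP-1 genes FOSB and JUNB 2.96-fold and 2.32-fold, the nuclear receptor gene NR4A1 2.65-fold, and ZFP36, whose product destabilises AU-rich mRNAs, 2.44-fold. JUN, the most abundant of the named members, rose 1.90-fold from 401 to 762 CPM. The member that fell was PLK2, a polo-like kinase gene, at −0.61 ± 0.10 (adjusted p = 0.00438), a call lost without vehicle library 1 or compound library 2 (adjusted p up to 0.0715). The list was shifted up by camera (adjusted p = 1.86e-37, and adjusted p = 0.0416 with an estimated correlation), with 18 to 23 members higher when any single library was left out and 2 lower without vehicle library 3.

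ERK feedback genes, the negative regulators and ETS factors transcribed in response to ERK signalling, rose in 9 of 20 cases and none fell (12 higher and 0 lower adjusted over the list alone). DUSP5, a phosphatase that acts on nuclear ERK, rose 3.96-fold from 5.67 ± 0.530 to 22.4 ± 2.06 CPM (1.99 ± 0.11, adjusted p = 8.60e-07). SPRY4, a Sprouty inhibitor of receptor tyrosine kinase signalling, rose 2.32-fold (adjusted p = 1.26e-06), and the transcription factor genes ETV5 and FOSL1 rose 1.64-fold and 1.69-fold. The list shares EGR1 and FOSL1 with the immediate early list. By camera it was shifted up (adjusted p = 1.69e-15, and adjusted p = 0.0288 with an estimated correlation), and 7 to 11 members were higher when any single library was left out. DUSP10, a phosphatase of stress-activated kinases that belongs to neither list, rose 2.53-fold (adjusted p = 0.00425), though not without vehicle library 1 (adjusted p = 0.0638).

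**Figure D2:**
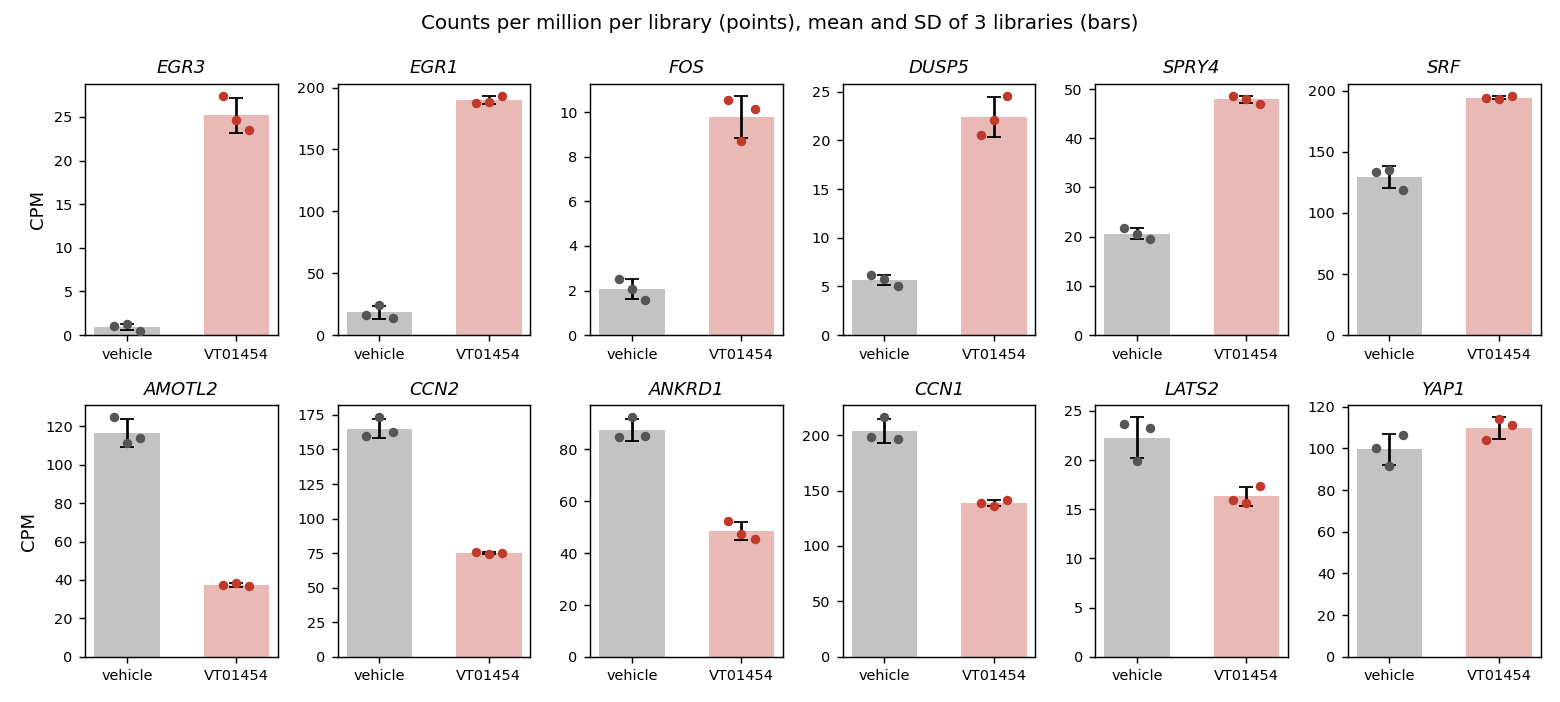
Levels in CPM of 12 genes in each library (points), with the mean and SD of the 3 vehicle (grey) and 3 compound (red) libraries, on axes that start at 0. EGR3, EGR1, FOS, DUSP5, SPRY4 and SRF were higher in every compound library than in any vehicle library, AMOTL2, CCN2, ANKRD1, CCN1 and LATS2 were lower in every one, and the groups overlapped for YAP1.

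Targets of serum response factor (SRF) and its MRTF co-factors, many of them cytoskeletal, rose in 9 of 30 cases with none falling (13 higher and 0 lower adjusted over the list alone). TRIB1, a pseudokinase gene, rose 1.74-fold (0.80 ± 0.06), SRF itself 1.503-fold from 129 to 194 CPM, and the actin-binding protein genes LIMA1 and TPM4 1.44-fold and 1.302-fold. Camera placed the list higher (adjusted p = 3.14e-09, and adjusted p = 0.0367 with an estimated correlation), but only 5 members were higher without vehicle library 1 or any single compound library, and 13 were higher and 1 lower without vehicle library 3. FOXO targets, which rise when AKT signalling falls, rose in 4 of 24 cases with none falling: IRS2 1.38-fold, CCNG2 1.33-fold, FBXO32 1.36-fold and FOXO3 1.31-fold. Adjusted over the list alone, 11 FOXO targets were higher and 1 lower, and camera gave an adjusted p = 4.73e-04, with adjusted p = 0.216 with an estimated correlation. Of these 4 genes, IRS2 passed without any single library. CCNG2 lost the call without vehicle library 1 or compound library 2 or 3 (adjusted p up to 0.134), and FBXO32 and FOXO3 without vehicle library 1 or any compound library (up to 0.147 and 0.231). Without vehicle library 3, 12 FOXO targets were higher and 1 lower; 2 were higher without compound library 1, and 1 without vehicle library 1, compound library 2 or compound library 3. DESeq2 also had 1 lower, beside 8 higher.

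Most listed transcripts of the Hippo pathway itself and of phosphoinositide enzymes stayed close to their vehicle levels. AMOTL2 and LATS2, which fell, were listed among the YAP/TAZ targets and not among the 44 Hippo components. Of 44 Hippo components, STRN3, a scaffold of the phosphatase complex that opposes the MST kinases, rose 1.299-fold (adjusted p = 0.0114) and TAOK2, a kinase upstream of the cascade, fell 1.31-fold (adjusted p = 0.0102); 42 did not pass, and both calls were lost without vehicle library 1 or any single compound library (adjusted p up to 0.104 and 0.102). Adjusted over the list alone, 2 were higher and 2 lower. The log2 fold changes were 0.14 ± 0.07 for YAP1, 0.26 ± 0.08 for WWTR1, the TAZ gene, and 0.21 ± 0.11 for TEAD1, and none of these passed (adjusted p = 0.381, 0.120 and 0.434). None of the 61 tested genes for PITPs and phosphoinositide metabolism passed in edgeR, DESeq2 or limma-voom. In edgeR 6 had an unadjusted p below 0.05, where 2239 of all 15577 tested genes did. Adjusting over the list alone gave 0 calls. PITPNA and PITPNB, which encode the class I PITPs, differed by −0.017 ± 0.06 and 0.045 ± 0.06 (adjusted p = 0.923 and 0.746). Camera with the preset correlation placed both lists slightly higher (adjusted p = 0.0468 for Hippo components and 0.0219 for phosphoinositide genes), with adjusted p = 0.664 and 0.663 with an estimated correlation. Without vehicle library 2 neither camera call held (adjusted p = 0.526 and 0.469), nor did that of Hippo components without compound library 2 (0.0841). Both were also lost with DESeq2 (0.0820 and 0.0737) and with offsets for GC content and gene length (0.427 and 0.251), and Hippo components passed in 8 of 18 alternatives. Without vehicle library 3, 11 Hippo components were higher and 2 lower, and 6 phosphoinositide genes were higher and 2 lower.

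**Figure D3:**
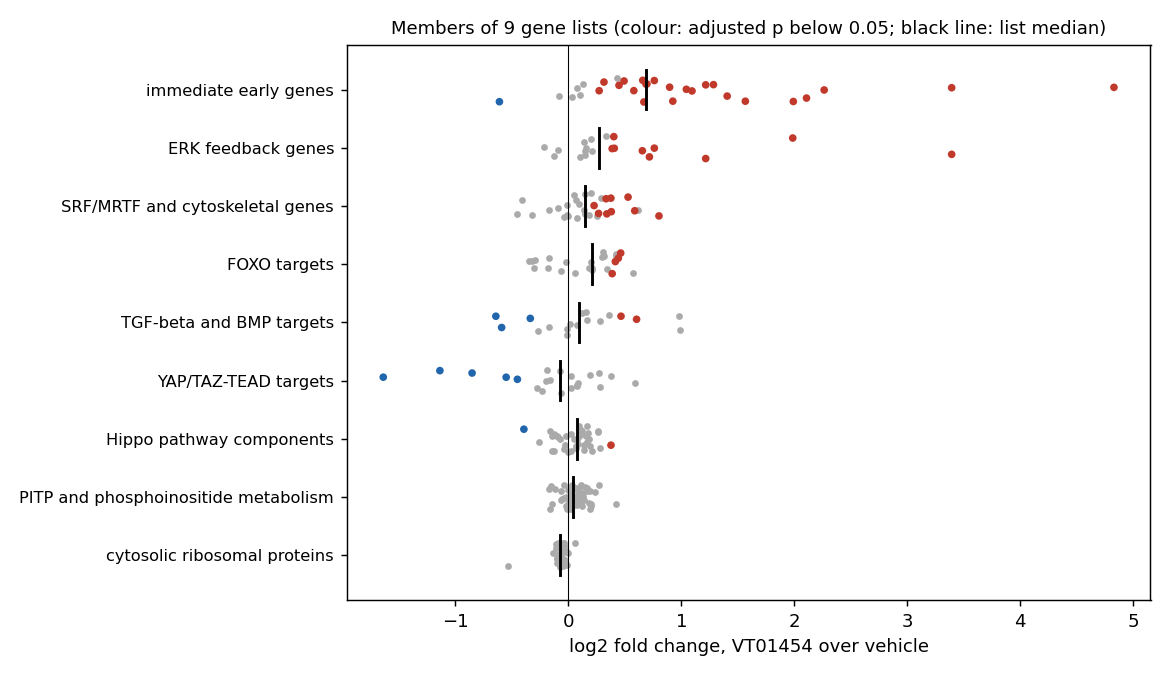
Log2 fold change of each tested member of 9 gene lists, coloured where the adjusted p was below 0.05, with the list median as a black line. The immediate early list has its median at 0.69 and reaches 4.83, the 5 coloured YAP/TAZ-TEAD targets lie between −1.64 and −0.45, and no phosphoinositide or ribosomal protein gene is coloured.

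Other lists moved in few members. Among 18 TGF-beta and BMP targets, PMEPA1 and TGIF1 rose 1.52-fold and 1.38-fold, while 3 fell, among them the BMP-responsive ID3 and ID1 (−0.59 ± 0.08 and −0.64 ± 0.11); 3 were higher and 3 lower adjusted over the list alone. Of 22 p53 targets 3 rose, the antiproliferative gene BTG2, the BH3-only gene BBC3 and the cell cycle inhibitor gene CDKN1A, by 1.59-fold, 1.62-fold and 1.23-fold (3 higher and 0 lower adjusted over the list alone), although the list median was −0.048, its mean −0.016 and its camera direction up. BTG2 is also on the immediate early list and counts among the rises there. Single members rose in 4 further lists: DNAJB9 in the unfolded protein response (1.48-fold), PPP1R15A in the integrated stress response (1.22-fold), SOX4 among Wnt targets (1.32-fold) and HEY1 among Notch targets (1.26-fold). Adjusted over the list alone these 4 lists had 2, 1, 1 and 2 members higher and 0 lower. The integrated stress response had a median of 0.016 and a mean of −0.030. None of these 6 lists passed camera (adjusted p = 0.336 for TGF-beta and BMP, 0.985 for p53, 0.463, 0.669, 0.104 and 0.336 for the other 4 in the order named), but Notch targets passed as higher with a term for library pairs (adjusted p = 1.76e-04) and Wnt targets without a count filter (0.0259). Without vehicle library 3 the members higher and lower were 6 and 3 for TGF-beta and BMP, 5 and 2 for p53, 3 and 3 for the unfolded protein response, 4 and 1 for the integrated stress response and 3 and 0 for Wnt. Without vehicle library 2 the unfolded protein and integrated stress responses had 2 higher each and p53 targets 2. Without vehicle library 1 or any compound library the unfolded protein response, integrated stress response and Notch lists had 0, p53 targets 1 or 2 higher, and TGF-beta and BMP targets 0 to 2 higher and 1 or 2 lower. Of the 12 genes that changed in this group only ID3, BTG2 and SOX4 passed without any single library; the rest lost the call in most cases without vehicle library 1 or a compound library, and BBC3 also without vehicle library 2 (adjusted p up to 0.265 for CDKN1A). No member changed in 13 tested lists holding 300 genes, of which 5 passed in DESeq2 and 0 in limma-voom. In edgeR 32 of the 300 had an unadjusted p below 0.05, where 2239 of all 15577 tested genes did. Without vehicle library 3 members did pass: 6 G2/M, 2 lysosome, 2 hypoxia, 1 fatty acid and 1 heat shock gene higher, 2 cholesterol genes higher and 1 lower, 1 G1/S gene each way, and 1 NF-kB target and 1 fibroblast or endothelial marker lower. Without vehicle library 2, 2 cholesterol genes and 1 hypoxia gene were higher and 1 G2/M gene lower. Beside the phosphoinositide list these were, with their camera adjusted p, cholesterol biosynthesis (0.674), fatty acid synthesis (0.336), heat shock (0.336), hypoxia and glycolysis (0.0611), NF-kB targets (0.453) and lysosome and autophagy genes (0.201). The others were G1/S genes (0.985), G2/M genes (0.172), interferon-stimulated genes (0.985), histones (0.947), fibroblast and endothelial markers (0.425) and ribosomal proteins. Adjusted over the list alone, cholesterol biosynthesis had 2 higher and 1 lower, hypoxia and glycolysis 1 higher, fibroblast and endothelial markers 1 lower, and the rest 0. Fatty acid synthesis had a median of 0.047 and a mean of −0.0083, and interferon-stimulated genes a median of −4.6e-04 and a mean of 0.015. Ribosomal protein genes had a median of −0.072 and a camera adjusted p = 0.0168 (adjusted p = 0.739 with an estimated correlation), and their median turned to 0.027 without vehicle library 2. That call was lost without vehicle library 2, compound library 2 or compound library 3 (adjusted p = 0.0855, 0.0554 and 0.0766), and 6 members were lower without vehicle library 3. Without vehicle library 2 the heat shock and hypoxia lists passed camera (adjusted p = 0.0126 and 0.0114). Only 1 leukocyte and 3 squamous epithelial markers were abundant enough to test, and none of the 4 passed. The squamous list reached 5 tested members and passed camera as lower without vehicle library 3, compound library 2, compound library 3 or both of these compound libraries (adjusted p = 0.01005, 0.0243, 0.0489 and 0.0132), and 2 of its members were lower without vehicle library 3.

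The remaining large falls were of mixed reliability. EIF5, which encodes a translation initiation factor, fell 2.05-fold from 418 ± 25.2 to 204 ± 4.06 CPM (−1.04 ± 0.06, adjusted p = 9.54e-07). The homeobox gene DLX5, the mitochondrial micropeptide gene MTLN, the carnitine palmitoyltransferase gene CPT1C and the non-coding PPP1R26-AS1 and MOCS2-DT fell 1.67-fold to 2.00-fold from 4.42 CPM or more in vehicle, or from 2.59 CPM for DLX5; of these MOCS2-DT alone passed without any single library, while the others lost the call without vehicle library 1 or any compound library, and MTLN and CPT1C also without vehicle library 2 (adjusted p up to 0.223). Among lower genes 23 of 96 were not protein-coding, against 2 of 198 higher genes. The 3 steepest falls were of low transcripts: PEG3, an imprinted zinc finger gene (4.62 to 0.261 CPM, −4.03 ± 0.68, adjusted p = 0.0393), the aminopeptidase gene ANPEP (1.71 to 0.346 CPM, −2.22 ± 0.50, adjusted p = 0.0468) and TMEM30B, a flippase subunit gene (1.93 to 0.415 CPM, −2.18 ± 0.46, adjusted p = 0.0341). All 3 calls were lost without vehicle library 1 or compound library 3, those of PEG3 and ANPEP without vehicle library 2, that of ANPEP without compound library 2 and that of TMEM30B without compound library 1 (adjusted p up to 0.185 for PEG3, 0.271 for ANPEP and 0.174 for TMEM30B). The size of the falls moved as well: without compound library 1 PEG3 stood at −6.65 and ANPEP at −3.01, without vehicle library 2 TMEM30B at −1.64, and PEG3 had 20, 0 and 2 counts in compound libraries 1, 2 and 3.

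The libraries also differed in a way that did not follow the groups. A set of 17 genes had at most 1 count per library on average in 2 or 4 libraries and at least 10 in each of the others. The sets of libraries involved formed 3 separate pairs: vehicle 1 with 2, vehicle 3 with compound 1, and compound 2 with 3. These pairs stood alone only at this minimum of 10 counts, chosen after the data were seen. With a minimum of 5 counts they alone lacked 22, 9 and 10 genes and alone held 8, 15 and 9. Other pairs then had such genes too: compound 1 and 3 alone held 11, and vehicle 2 and compound 3 alone lacked 6. CRH, the corticotropin-releasing hormone gene, had 272, 434 and 248 counts in vehicle and 188 in compound 1, but 0 in compound 2 and 3; PENK, DLK1, CP, HGF and PEG3 followed the same libraries. The 6 genes summed to 27.5, 49.98 and 22.6 CPM in vehicle and to 14.1, 0.0399 and 0.162 CPM in compound libraries 1, 2 and 3. When the library pair was fitted as a term, the treatment effect rested on vehicle 3 and compound 1 alone and 50 genes passed, 44 of them among the 294; 280 of the 294 kept at least 0.5 of their log2 fold change. These genes were selected with the same libraries and their groups did not overlap. That fixed the kept direction and left little room for the kept size, so neither decides on the pairs. In that fit 15 immediate early, 6 ERK feedback and 3 SRF targets were higher, 3 YAP/TAZ targets (AMOTL2, CCN2 and ANKRD1) were lower, and no FOXO target passed. AMOTL2 stood at −1.61 ± 0.11, CCN2 at −1.10 ± 0.09 and EGR3 at 5.72 ± 0.24, whereas ANPEP went to −0.42 ± 0.54 and the ribosomal protein list passed camera in the opposite direction, as higher (median 0.12, adjusted p = 3.17e-06). With compound libraries 2 and 3 left out, 44 genes passed, among them 13 immediate early genes higher and 3 YAP/TAZ targets lower, with the lone compound library assumed to vary like the vehicle libraries.

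**Figure D4:**
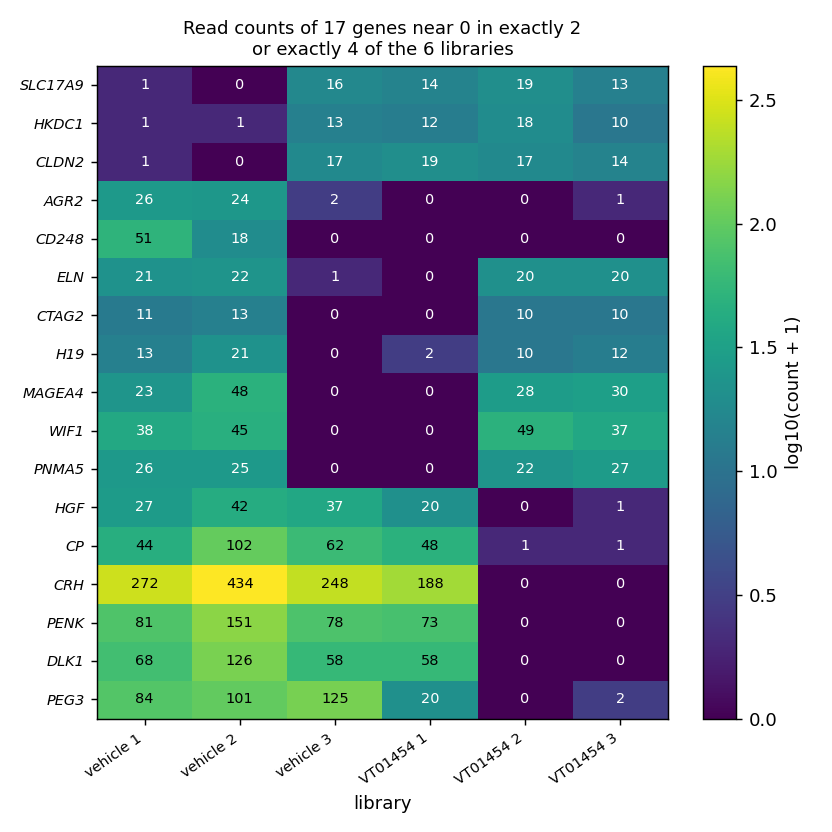
Read counts of the 17 genes that were near 0 in exactly 2 or exactly 4 of the 6 libraries, printed in each cell and coloured by log10(count + 1). CRH is absent only from compound libraries 2 and 3, WIF1 only from vehicle 3 and compound 1, and CD248 is counted only in vehicle 1 and 2.

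The number of changed genes depended on single libraries. It was 93 without vehicle library 1 and 136, 109 and 108 without compound libraries 1, 2 and 3, but 1806 without vehicle library 3; without vehicle library 2 it was 414, and the number of lower genes went from 96 to 159. All 294 genes had groups that did not overlap, as did 21.1% of tested genes, where chance gives 10%.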

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

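The GC and length offsets, thinning, covariate, library pair term and omission of 2 compound libraries were chosen after the data were seen; the other alternatives were set before the data were examined. DESeq2 called 427 genes, DESeq2 size factors 293, library size alone 271, limma-voom 277, a mean of 1 CPM 290 and thinning to the smallest library 285, so the count changed little at equal depth. Without a count filter 713 genes passed (508 higher, 205 lower), and with GC and length offsets 694 (426 and 268), 291 of the 294 among them. A 1.5-fold minimum left 92 genes and an adjusted p below 0.01 left 125, by construction. The count was 36 (30 and 6) with the covariate, 44 (38 and 6) without compound libraries 2 and 3, and 50 (40 and 10) with the library pair term; these fits have fewer samples or more terms.

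Leaving out single libraries moved genes changed between 93 and 1806, genes higher between 73 and 1170, genes lower between 20 and 636, SRF targets higher between 5 and 13, and the YAP/TAZ list median between −0.12 and −0.041. That list lost its camera call without vehicle library 3 (median −0.057, adjusted p = 0.116) and with an estimated correlation (median −0.071, adjusted p = 0.206), and passed in the other 17 fits. YAP/TAZ targets lower were 3, 3 and 3, immediate early genes higher 12, 13 and 15, and SRF targets higher 1, 1 and 3 with the covariate, without 2 compound libraries and with the pair term. The number of lists past camera was 5 with the offsets, 5 with the covariate and 3 with an estimated correlation, against 8. Lists gained were hypoxia, Wnt and G2/M without a filter (adjusted p = 0.00544, 0.0259 and 0.0352), hypoxia and Notch with the pair term (0.0181 and 1.76e-04), heat shock and hypoxia without vehicle library 2 (0.0126 and 0.0114), and squamous epithelium in 4 fits that left out libraries (0.01005 to 0.0489). Hippo components were lost in 10 of 18 fits, among them DESeq2 (0.0820), library size alone (0.0796), a mean of 1 CPM (0.0591), limma-voom (0.0521) and the offsets (0.427), and phosphoinositide genes in 6 of 18, among them DESeq2 (0.0737) and the offsets (0.251). The cause was not tested except where fewer samples or more terms reduce power. By the directional fry test YAP/TAZ targets passed as lower, and SRF, immediate early, ERK feedback and FOXO lists as higher. Hypoxia and Wnt lists also passed fry as higher (adjusted p = 0.0138 and 0.0194). Hippo components, phosphoinositide genes and ribosomal proteins did not pass fry (adjusted p = 0.546, 0.361 and 0.675).

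Sign changes were seen in genes that had not passed, in the medians of the Hippo and ribosomal protein lists, which had passed as lists, and in at least 1 fit in the medians of 11 lists that had not passed: cholesterol, p53, G1/S, interferon, unfolded protein response, integrated stress response, Notch, histones, leukocytes, fibroblasts and endothelium, and squamous epithelium. AXL ran from −0.068 to 0.20 and PITPNA from −0.049 to 0.0086 over fits that left out 1 library, and the ribosomal protein list median from −0.14 to 0.027. With the offsets PITPNA was 0.0028 and PITPNB −0.0063. With the covariate YAP1 was −0.0072, TEAD1 −0.024, PITPNA 0.040 and RPS6 0.0083, the Hippo list median −0.0033 and the ribosomal median 0.055. Without 2 compound libraries PITPNA was 0.047. With the pair term YAP1 was −0.035, TEAD1 −0.14, AXL −0.16, PITPNA 0.022, PITPNB −0.012, RPS6 0.051 and RPL11 0.065, the Hippo median −0.029 and the ribosomal median 0.12, where the ribosomal list passed camera as higher (adjusted p = 3.17e-06), opposite to the call as lower. The cause was not tested. Of the values of single named genes, 1093 kept their direction and side of the threshold, 205 lost the call, 30 gained one and 20 changed sign.

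The replicate number as a block gave 339 genes changed, 267 of the 294 among them, and changed no list call. The numbers do not pair the samples: deviations of same-numbered libraries correlated at −0.067, 0.017 and −0.0045. Leaving out mitochondrially encoded genes was not run, because these were at 0 and none was tested. With 3 libraries per group, simulated changes of 1.3-fold were recovered in 38% of cases, so smaller effects were mostly out of reach.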

Other observations

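The falls included genes that the fixed lists do not hold, chosen here after their values were seen. AJUBA, which encodes a LIM protein that binds LATS kinases, fell 1.45-fold (78.7 ± 3.45 to 54.1 ± 1.90 CPM, adjusted p = 4.63e-04, edgeR), and the long non-coding RNA NEAT1, a scaffold of nuclear paraspeckles, fell 1.65-fold (80.8 ± 3.35 to 49.1 ± 0.0994 CPM, adjusted p = 3.02e-05). The CDC-like kinase genes CLK1, CLK4 and CLK3, whose products phosphorylate SR splicing factors, rose 2.08-fold, 1.69-fold and 1.46-fold. All 5 kept their call without any single library, and CLK1, CLK4 and NEAT1 also passed with the library pair term.

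The protein-coding genes that fell were short. Their median span on the genome was 12.7 kb (73 genes), against a median of 36.6 kb over 10000 random lists of tested protein-coding genes matched on mean expression (95% of lists between 25.4 and 52.4 kb), and no random list was as low. The 196 protein-coding genes that rose had a median span of 30.0 kb, against 37.9 kb (195 of 10000 lists as low). Exonic length did not stand apart in either direction (5.18 kb for genes that fell, at the 33.2 percentile of matched lists, and 5.57 kb for genes that rose, at the 59.8 percentile). Median GC content was 51.5% for genes that fell and 47.0% for genes that rose, at percentiles 96.3 and 12.1. These 6 medians were compared after the calls were known, and no explanation was tested.

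Of the tests below, those of library depth and of the compound on the CRH signal, and those of another source and of library pairs on the list genes, were chosen after the result was seen, as were the count minimums and the bootstrap interval of the second pattern. The GC and length offsets and the thinning were also chosen after the data were seen. The first pattern is the change of 36 members of the immediate early, ERK feedback and YAP/TAZ lists. RNA of another source would put compound library 1, which shares the CRH signal, part of the way from the other compound libraries to vehicle. The signal genes lie at 0.421 of that way when summed, and singly at 0.144 to 0.527. The test used 29 list genes called without compound library 1, so that the choice of genes did not set its place. Its median position was −0.0031 (95% bootstrap interval −0.053 to 0.041), which argues against another source as the whole cause. The highest list gene, at 0.200, lay within the range of single signal genes. The interval comes from resampled genes and does not measure how 1 library might vary. GC content and gene length are argued against as the whole cause, since 36 of 36 passed with GC and length offsets. After thinning 36 of 36 passed as well. Thinning keeps the share of each gene in its library apart from sampling, so it could hardly undo strong calls and cannot decide on library depth. With the pair term 22 of 36 still passed and 36 of 36 kept at least 0.5 of their log2 fold change. The genes had been selected with the same libraries, which all but fixed that size, so this fit cannot decide on pairs. Pairs as the whole cause would put compound library 1 near its partner, vehicle library 3. Over the same 29 genes the median position of compound library 1, −0.0031, argues against that, though it rests on 1 library. A part played by library pairs stays open. An effect of the compound stays open too. Splits of the libraries cannot decide on chance. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 294 genes and was the 1 split with so many. The highest of the other splits gave 1 gene, but 10 splits are too few for a share under 0.05. A mixed split also carries the group difference as spread. The edgeR calls set the 36 members apart from the spread between these libraries, which may be technical.

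The second pattern is the presence of CRH, PENK and DLK1 transcripts in 4 of 6 libraries. At the level of compound library 1, 353 counts of the 6 signal genes would be expected in compound library 2 and 1 was found. The genes were picked for that gap, so it decides nothing on library depth. The library totals, which played no part in the choice, argue against depth. Vehicle libraries 1 and 2 had totals of 20962083 and 19126039, below the 25066990 and 24646466 of compound libraries 2 and 3, yet held 576 and 956 signal counts. The compound as the cause stays open: compound library 1 held 139 times the mean summed CPM of the other compound libraries, but the genes were picked for that difference, and its 14.1 CPM lay below all 3 vehicle libraries. A small share of another source in 4 libraries may be the cause, but the test was open: at a minimum of 10 counts, 6 genes were missing only from compound libraries 2 and 3 and 0 were present only there, while at 5 counts these numbers were 10 and 9. Handling of the libraries in 3 pairs was tested on 4732 low genes outside the defining set, where the lowest of the 3 pairs ranked 8 of 15 by residual correlation (bootstrap interval 4 to 14), so it stays open too, as do differences between the cultures.

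The third pattern is RPS18, a ribosomal protein gene at 6p21, with 4 to 10 counts per library. Low expression of the gene is argued against: its mean of 0.301 CPM was 0.0697 of the lowest of the other 39 listed ribosomal protein genes, RPS9 at 4.31 CPM, and their median was 927 CPM. A candidate explanation is that reads at loci with a second copy in the genome index were not counted; between HLA-F and KIFC1 (chromosome 6, 29722775 to 33409924) 28 of 153 protein-coding genes passed the count filter, against 589 of 888 on the rest of the chromosome (odds ratio 0.114, Fisher's exact p = 5.11e-29), which goes with it but was found on the same data. The comparison did not account for how many genes of the window these cells express, and it treated neighbouring genes as independent. No biological explanation was tested.

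Apart from these patterns, 16 genes had at least 100 counts in 1 library and over 3 times the CPM of any other, among them LY6E (1113 counts in vehicle 3, 36 to 55 elsewhere), NOMO3 and KIFC1; 15 of the 16 were tested and 0 changed in edgeR.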
